A study of Mus musculus with 12 samples.

How the data were processed

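The study measured protein occupancy by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which formaldehyde fixes proteins to DNA, an antibody pulls down the fragments bound by 1 protein, and the fragments are sequenced and placed on the genome. Per the labels, the 12 libraries came from mouse embryonic stem cells of the wild-type lines A3 (strain 129X1/SvJ) and E14 (strain 129P2/OlaHsd) and from A3 cells lacking Zfp57. Each cell population gave an input library and libraries for ZFP57, KAP1 and H3K9me3, with 1 library per group. The values here come from 4 peak lists, those of ZFP57 and KAP1 in wild-type A3 and in E14. The other 8 libraries, among them every library of the Zfp57-deficient cells, the inputs and H3K9me3, were not analysed here, so no peak was compared with its level in cells without ZFP57.

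The deposited files list peaks called by the authors, 1 list per library, with 3 columns for chromosome, start and end. They carry no score, enrichment, read count or p-value. The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.7, SAMtools 0.1.18 and bedtools 2.14.3-1 and the genome build mm9. The peak caller, its threshold, the use of the input and any filter are not given in the sources used here. In the deposited files every start lay 1 above a multiple of 150 and every end on a multiple of 150, so positions were read as 1-based windows of 150 bp, and a width or offset cannot be known more finely than that. The depth of the libraries is unknown, and the length of a list moves with depth and threshold, so the numbers of peaks were not read as amounts of binding.

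The mm9 genome and its gene models were not used here. The gene table at hand is of the assembly GRCm38.p6, and 86 peaks on 8 chromosomes lay beyond the last gene it holds there, so its coordinates were not applied. Peaks are therefore given by mm9 position and not by gene, exon, intron or UTR. The planned tests of gene context, gene lists (imprinted, KRAB zinc finger, pluripotency, germ cell, lineage and ribosomal protein genes), sequence motif, base composition and repeats were not run. The planned comparisons of peak scores were not run because the lists hold no score.

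Peaks that overlapped or touched within a list were merged, which removed 1 peak from the A3 ZFP57 list, 53 from A3 KAP1, 1 from E14 ZFP57 and 3 from E14 KAP1. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Chance was estimated by placing the peaks of the first list 1000 times at random, each on its own chromosome and at its own width, up to the last peak end on that chromosome in any list. The one-sided p of this test cannot go below 0.001. Placement ignores the parts of the genome where reads cannot be mapped, and it tests the peak lists, not the cell lines. A site is the union of overlapping peaks of the 4 lists. Shares of peaks have 95% exact Clopper-Pearson intervals, which cover counting error only, and peaks are not replicates. Where no peak was found, the upper limit given is 3 counts of the total, which is not a Clopper-Pearson limit. Two-sided Fisher's exact tests compared shares of peaks, with Benjamini-Hochberg adjustment over the 21 chromosomes for each protein. Widths were compared within a list by a two-sided permutation test of mean rank with 100000 resamples, whose smallest p is 1e-05, and chromosome distributions by a two-sided permutation chi-square test of the same size. With 1 library per group, no test here measures variation between cultures.

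The rule for naming peaks was fixed before the data were examined. It took the 10 widest peaks of each ZFP57 list, the 5 widest of each KAP1 list and, of the sites called in all lists, the 15 with the widest A3 ZFP57 peak, width standing in for the absent score. Alternatives fixed then were a reciprocal overlap of 50%, a distance of 1 kb, the wider part of each list (peaks of at least 450 bp for both ZFP57 lists and E14 KAP1, at least 600 bp for A3 KAP1, the width limits that keep closest to 50% of each list) and the autosomes alone. Leaving out peaks wider than 1500 bp, leaving out chromosomes 1, 2, 8 and 14, and a chance level from moving each peak by 50 to 500 kb were added after seeing the data, as were the width comparisons, the Fisher's exact tests between the lines (the share of ZFP57 peaks with KAP1, and each chromosome) and the test of ZFP57 at line-shared KAP1 peaks. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The overlap count was tested on simulated data against bedtools 2.31.1. With 1484 peaks of the A3 ZFP57 list placed at random and 50 made to coincide with simulated E14 ZFP57 peaks, 50 were found, and with 0 made to coincide, 0 were found. With 500 simulated E14 KAP1 peaks made to coincide with simulated A3 KAP1 peaks, 504 were found, where random placement gave a mean of 4.50.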

Results

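The study set ZFP57, KAP1 and H3K9me3 occupancy in mouse embryonic stem cells lacking Zfp57 against that in wild-type cells. ZFP57 is a zinc finger protein with a KRAB domain that is known to act at imprinted regions, and KAP1 (TRIM28) is the corepressor that KRAB zinc finger proteins recruit. The wild-type peak lists of both proteins in the lines A3 and E14 allowed comparison of the lines and of the proteins within each line. The A3 ZFP57 list held 1485 peaks covering 0.713 Mb, and the E14 ZFP57 list held 602 peaks covering 0.337 Mb. The A3 KAP1 list held 10295 peaks covering 6.09 Mb, and the E14 KAP1 list held 1334 peaks covering 0.671 Mb. Median peak width was 300 bp for A3 ZFP57, 600 bp for A3 KAP1 and 450 bp for both E14 lists. There was 1 library per group, so no value has a replicate error.

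The first comparison asked which ZFP57 peaks were called in both wild-type lines. A total of 56 peaks were shared, which was 3.77% of the A3 list (95% exact interval 2.86 to 4.87%) and 9.30% of the E14 list (7.10 to 11.9%). In 1000 random placements of the A3 peaks at most 3 fell on an E14 ZFP57 peak, with a mean of 0.370 (one-sided permutation p = 0.001, the smallest they can give). Peaks found in both lines were the wider ones of each list. In A3 their median width was 600 bp against 300 bp for the others, and 3.57% against 56.0% had the minimum width of 300 bp. In E14 the medians were 600 bp and 450 bp, and 0 of the 56 shared peaks against 46.9% of the others had the minimum width, where 0 of 56 allows a share of up to 5.36% by the limit of 3 counts of the total. Both differences passed the permutation test of widths (p = 1e-05, the smallest it can give). Among the wider peaks of each list, of at least 450 bp, 54 were shared, which was 7.91% of A3 and 15.6% of E14, and without chromosomes 1, 2, 8 and 14 the shared part of the A3 list was 5.91%.

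The second comparison asked how often KAP1 was called at ZFP57 peaks of the same line. In E14, 160 of the 602 ZFP57 peaks overlapped a KAP1 peak (26.6%, 23.1 to 30.3%), against at most 4 in random placements (permutation p = 0.001), and 39.9% did in the wider part of each list. In A3, 63 of the 1485 ZFP57 peaks did (4.24%, 3.28 to 5.40%), against at most 14 in random placements (permutation p = 0.001). The E14 share was 6.26 times the A3 share (Fisher's exact test over peaks, p = 2.7e-45). Seen from KAP1, 12.0% of the E14 KAP1 peaks (10.3 to 13.9%) and 0.612% of the A3 KAP1 peaks (0.471 to 0.782%) overlapped a ZFP57 peak of the same line. ZFP57 peaks with KAP1 were also wider than those without, with medians of 600 bp and 300 bp in both lines (permutation p = 1e-05 in each).

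ZFP57 peaks present in both lines carried KAP1 more often than ZFP57 peaks of 1 line alone. In A3, 38 of the 56 line-shared peaks had a KAP1 peak (67.9%, 54.0 to 79.7%), against 25 of 1429 peaks called in A3 alone (1.75%, 1.14 to 2.57%). The odds ratio was 119 (Fisher's exact test over peaks, p = 9.6e-45), 77.2 when peaks within 1 kb counted as shared and 171 on the autosomes. In E14, 51 of the 56 line-shared peaks had a KAP1 peak (91.1%, 80.4 to 97.0%), against 109 of 546 called in E14 alone (19.96%, 16.7 to 23.6%). The odds ratio was 40.9 (Fisher's exact p = 6.5e-27), and 12.5 among the wider peaks of each list. Of the 56 peaks, 5 had KAP1 in neither line. Most ZFP57 peaks met no peak of any other list: 1393 in A3 (93.8%, 92.5 to 94.98%) and 421 in E14 (69.9%, 66.1 to 73.6%). Lists of 1 line may share an input control or a background, and the sources used here do not say whether they did.

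**Figure D1:**
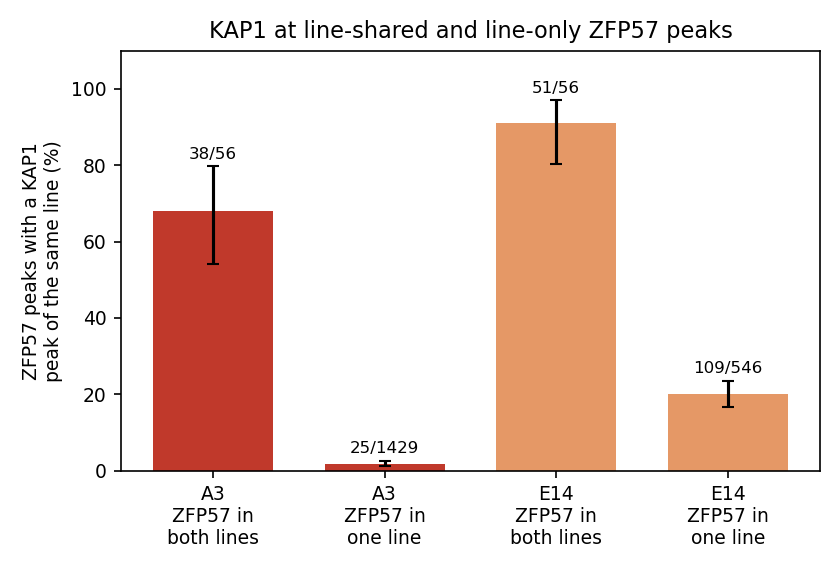
Percent of ZFP57 peaks that overlap a KAP1 peak of the same line (bars start at 0, error bars are 95% exact intervals, counts above), for ZFP57 peaks called in both lines and in 1 line only. The share is 67.9% against 1.75% in A3 and 91.1% against 19.96% in E14.

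The third comparison joined all lists, and 38 sites were called for ZFP57 and KAP1 in both lines. They had a median width of 750 bp and lay on chromosomes 2, 4 to 18 and X. Chromosomes 7 and 12 held 6 each, and chromosomes 4, 11 and 13 held 3 each. None lay on chromosomes 1, 3, 19 or Y, although chromosome 1 held 203 A3 ZFP57 peaks. The midpoints of the A3 and E14 ZFP57 peaks lay within 150 bp of each other at 37 of the 38 sites. The ZFP57 and KAP1 midpoints lay within 150 bp at 35 sites in A3 and at 35 in E14. A further 42 sites had KAP1 in both lines and ZFP57 in E14, and 4 had KAP1 in both lines and ZFP57 in A3. Another 13 sites had ZFP57 in both lines and KAP1 in E14.

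**Figure D2:**
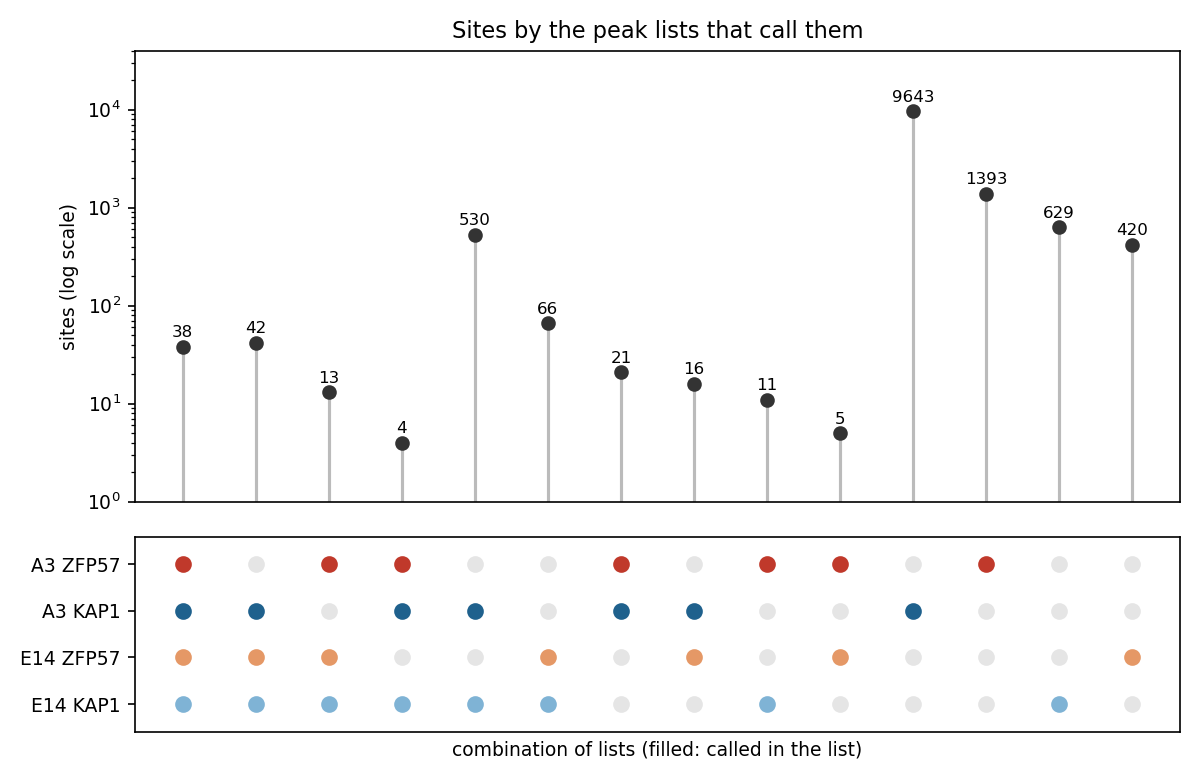
Number of sites (log axis) for each combination of the 4 peak lists, with filled circles marking the lists that call the site. The 38 sites called in all lists stand at the left, and the 9643 and 1393 sites called by A3 KAP1 alone and A3 ZFP57 alone stand toward the right.

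The 15 sites with the widest A3 ZFP57 peak, in mm9 coordinates, were these. The widest was on chromosome 9 at 2999851 to 3003300, where each list had a peak of exactly 3450 bp. The boundaries there were the same in all lists, and whether the site reflects binding or a background common to the libraries was not tested. The chromosome 2 site at 157385101 to 157386450 had ZFP57 peaks of 1200 bp and KAP1 peaks of 1350 bp in both lines. The other chromosome 2 site lay at 174121051 to 174122100, with a ZFP57 peak of 750 bp in each line. On chromosome 7 the site at 67148851 to 67150200 had a ZFP57 peak of 1200 bp in A3 and 600 bp in E14. The chromosome 7 site at 134754301 to 134755950 had ZFP57 peaks of 1200 bp in A3 and 1500 bp in E14, and another at 6681601 to 6682500 had peaks of 750 bp and 600 bp. The chromosome 8 site at 125388751 to 125389650 had ZFP57 peaks of 900 bp in A3 and 750 bp in E14. All lists had a peak of 900 bp at 74520001 to 74520900 on chromosome 18, and a peak of 750 bp at 140379301 to 140380050 on chromosome 4 and at 6324451 to 6325200 on chromosome 17. A second site on chromosome 9 lay at 89774251 to 89775000. Chromosome 10 held sites at 12810151 to 12811350 and at 79201801 to 79203150. The remaining named sites were on chromosome 13 at 47106001 to 47106750 and on chromosome 15 at 72639901 to 72640950. At these last 5 sites the A3 ZFP57 peak was 750 bp wide.

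**Figure D3:**
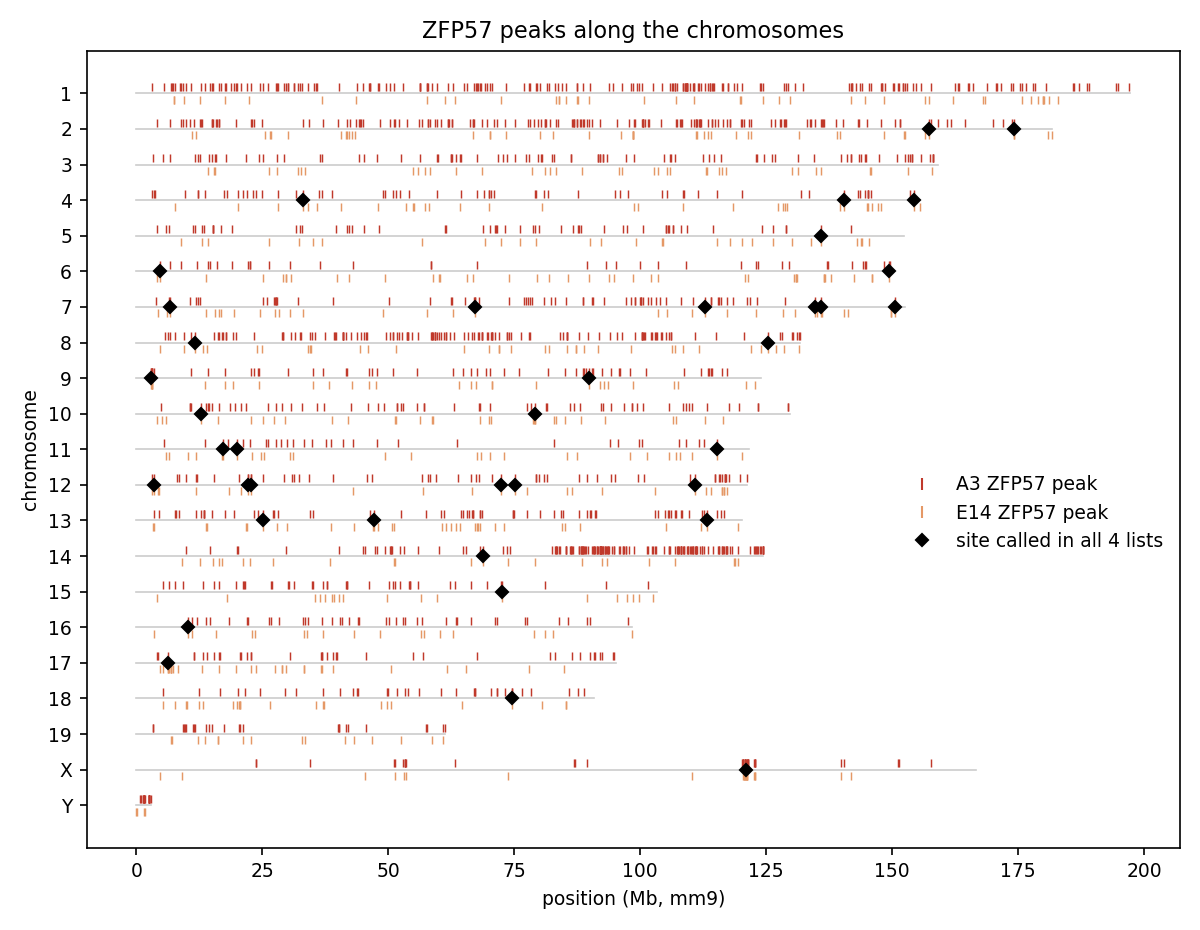
Position in Mb (mm9) of every A3 ZFP57 peak (upper ticks) and E14 ZFP57 peak (lower ticks) on each chromosome, with black diamonds at the 38 sites called in all 4 lists. A3 peaks crowd the distal part of chromosome 14, which holds none of the diamonds beyond 80 Mb.

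The widest ZFP57 peaks were mostly not among these sites. The A3 list was led by a peak of 22950 bp on chromosome Y at 2849551 to 2872500, called in no other list. A region of chromosome 1 at 87479251 to 87498150 was called at a width of 18900 bp by both E14 lists, and A3 ZFP57 called 87479101 to 87498150 there, while A3 KAP1 did not. Chromosome 9 between 2999851 and 3038400 held 4 of the 10 widest peaks in the A3 list and 4 of the 10 widest in the E14 list. Chromosome 4 held wide ZFP57 peaks that the other line did not call at the same place, at 145146451 to 145153200 and 145705351 to 145709250 in A3 and at 145038301 to 145044600 and 146017351 to 146021550 in E14. The others were called in A3 alone on chromosome X at 120113551 to 120119700 and on chromosome 12 at 94123801 to 94129650, and in E14 without A3 ZFP57 on chromosome 1 at 85266301 to 85282950 and on chromosome 5 at 130162651 to 130164450. The tenth E14 peak, on chromosome 6 at 149310001 to 149311650, was 1 of the 38 sites.

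For KAP1, 614 peaks were shared between the lines. They made up 46.0% of the E14 list (43.3 to 48.7%) and 5.96% of the A3 list (5.51 to 6.44%), against at most 13 in random placements of the E14 peaks (permutation p = 0.001). In A3, shared KAP1 peaks carried ZFP57 more often than A3-only ones, with 42 of 614 (6.84%) against 21 of 9681 (0.217%) and an odds ratio of 33.8 (Fisher's exact test over peaks, p = 8.2e-37). In E14 the shares were 81 of 614 (13.2%, 10.6 to 16.1%) and 79 of 720 (10.97%, 8.78 to 13.5%), which did not differ past the threshold (odds ratio 1.23, Fisher's exact p = 0.237). The widest A3 KAP1 peak was 13950 bp on chromosome 17 at 6255001 to 6268950. The next lay on chromosome 13 at 12913651 to 12919500 and 12980401 to 12984300, chromosome 16 at 3121501 to 3126450 and chromosome 4 at 146709001 to 146713200. Only the first of the chromosome 13 peaks met an E14 KAP1 peak. In E14, after the chromosome 1 region, the widest were on chromosome 9 at 3021901 to 3033750, chromosome 8 at 19764601 to 19773300 and 19996651 to 20001750, and chromosome 5 at 146514451 to 146518050, and none of these met an A3 KAP1 peak.

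The last comparison was of the chromosomes on which the peaks lay. In A3, 22.1% of the ZFP57 peaks would have to move to another chromosome to match the KAP1 list, against 4.80% expected from chance (permutation chi-square test over 1485 and 10295 peaks, p = 1e-05). In E14 the figure was 8.43% against 8.65% (permutation p = 0.649), so a difference was not detectable with these list lengths. Chromosome 14 held 10.6% of the A3 ZFP57 peaks (9.12 to 12.3%) and 3.82% of the E14 ones (2.44 to 5.68%), an adjusted Fisher's exact p of 2.4e-06. Chromosome 1 held 13.7% (12.0 to 15.5%) and 7.14% (5.22 to 9.50%), with adjusted Fisher's exact p = 1.8e-04. By the same exact test chromosomes 6 and 11 held smaller shares in A3 than in E14, at 2.56% against 6.64% (adjusted p = 2.2e-04) and 2.15% against 4.65% (adjusted p = 0.0180). The counts there were close, with 38 A3 and 40 E14 peaks on chromosome 6 and 32 and 28 on chromosome 11. A share falls when the list gains peaks on other chromosomes. Chromosome 2, with 10.8% against 7.31%, and chromosome 8, with 9.02% against 5.98%, missed the threshold after adjustment (adjusted exact p of 0.0515 and 0.0646). So did chromosome 17 in the other direction, with 2.56% in A3 against 4.82% in E14 (adjusted exact p = 0.0515).

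**Figure D4:**
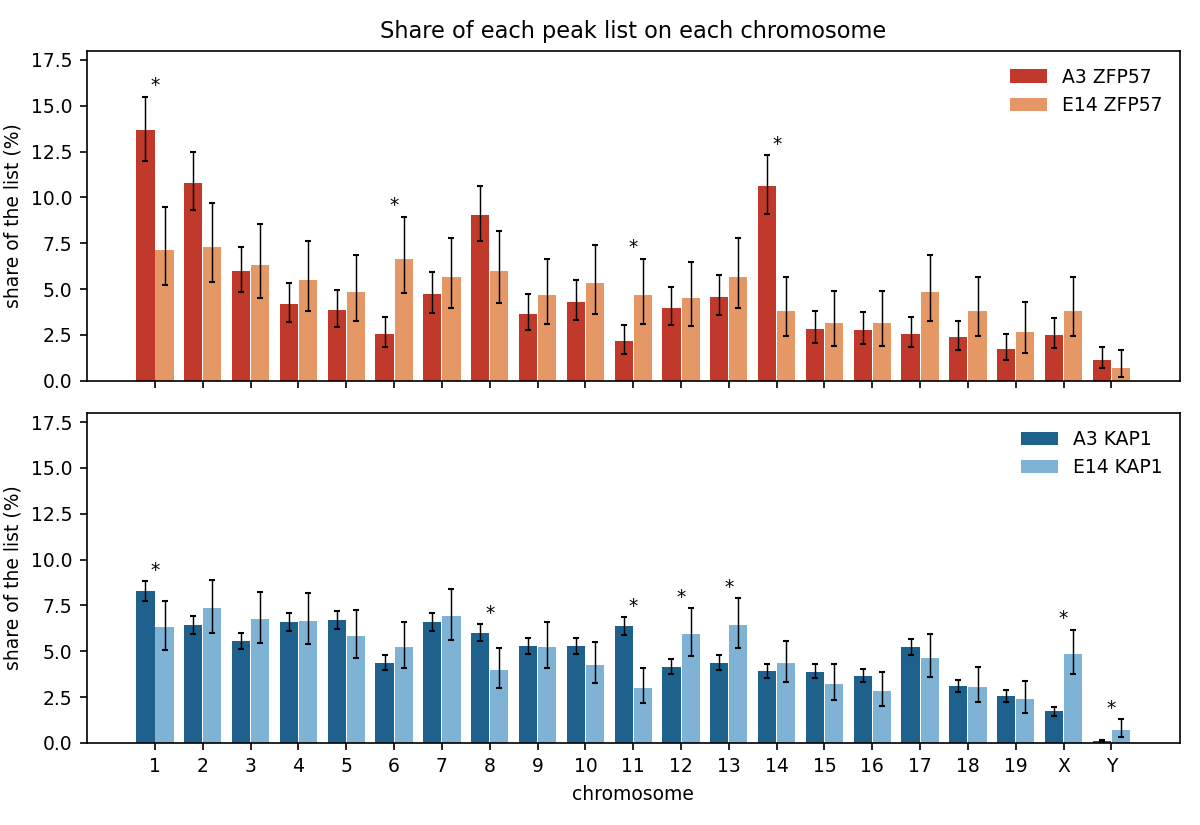
Share of each peak list on each chromosome in percent, A3 beside E14, for ZFP57 (top) and KAP1 (bottom), with 95% exact intervals and an asterisk where the adjusted Fisher p was under 0.05. A3 ZFP57 reaches 13.7% on chromosome 1 and 10.6% on chromosome 14.

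On chromosome 14 the A3 ZFP57 peaks were concentrated at the distal end. Beyond 80 Mb, 35.7% of the chromosome's span, lay 132 of its 158 A3 ZFP57 peaks (83.5%, 76.8 to 89.0%), against 8 of 23 E14 ZFP57 peaks (34.8%, 16.4 to 57.3%). The A3 KAP1 share there was 99 of 403 (24.6%, 20.4 to 29.1%) and the E14 KAP1 share 21 of 58 (36.2%, 24.0 to 49.9%). The boundary at 80 Mb was chosen after the positions were seen.

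**Figure D5:**
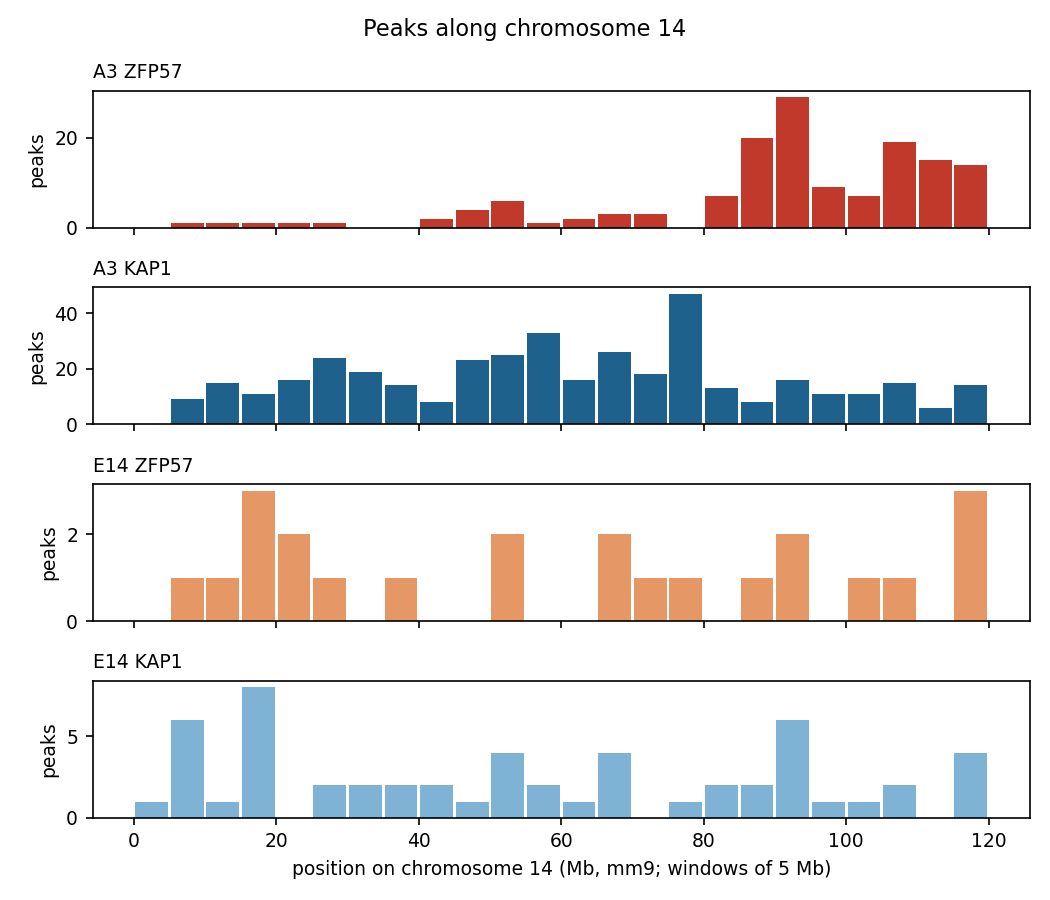
Number of peaks in each complete 5 Mb window of chromosome 14 (mm9) for the 4 lists, with bars from 0 and a separate vertical scale for each list. In the A3 ZFP57 list 132 of 158 peaks lie beyond 80 Mb, some of them past the last complete window and not drawn, while the other lists show no such step.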

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

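The tests of chromosome gain, of dense windows, width and KAP1 overlap on each chromosome by itself and of the KAP1 list swap were chosen after the results were seen, as were the test of how far the KAP1 lists nest and the comparisons between the lines of KAP1 shares and of chromosomes. An earlier single test of gain, which took the lower A3 to E14 ratio of KAP1 shares on chromosomes 1 and 14, was undecided (0.900 on chromosome 14, Fisher's exact p = 0.455), and the separate tests for chromosome 1, whole chromosome 14 and its distal part replaced it after that value was known. The other tests here were set before their values were seen, although the patterns themselves were noticed in the same data. Each result below stood out because the same measure differed between A3 and E14, each a single library per protein.

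The share of ZFP57 peaks with a KAP1 peak was 6.26 times higher in E14 than in A3. Dilution by narrow A3 calls does not account for the whole ratio, which was 6.64 in the wider part of each list. That setting also cut the KAP1 lists, at 600 bp in A3 and 450 bp in E14, so 6.64 does not give the effect of ZFP57 width alone. Very wide regions are argued against, because the ratio was 6.16 without peaks over 1500 bp. The ratio was 5.25 at a distance of 1 kb and 5.08 without chromosomes 1, 2, 8 and 14. A difference between the KAP1 lists does not account for the whole ratio either: against the A3 KAP1 list alone, 15.9% of E14 and 4.24% of A3 ZFP57 peaks overlapped, a ratio of 3.76, and against the E14 KAP1 list alone 26.6% and 4.44%, a ratio of 5.98. The A3 ZFP57 list itself may therefore hold many calls outside KAP1-bound sites, and whether these are weak binding, background of that library or a property of the line stays open. The strain and line difference was not tested, since each line has 1 ZFP57 library.

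A3 ZFP57 peaks took 1.91 times the E14 share on chromosome 1 and 2.78 times on chromosome 14. Narrow calls near the detection limit are argued against, because the odds of the minimum width were lower on these chromosomes (odds ratio 0.302, Fisher's exact p = 8.8e-22; 0.519 on chromosome 1 and 0.12 on chromosome 14), and so are a few dense windows of 1 Mb, because the 5 densest held 10.8% of the peaks on chromosome 1 and 22.2% on chromosome 14 (15.8% together), although the excess on chromosome 14 lay in its broad distal part, without which chromosome 14 held 1.92% of the A3 and 2.53% of the E14 ZFP57 peaks. Binding that carries KAP1 is argued against on chromosome 1. KAP1 overlap was rarer there than on the chromosomes without an excess (odds ratio 0.186, Fisher's exact p = 0.00514, and 0.316 for both chromosomes together). On chromosome 14 the same test could not decide (odds ratio 0.486, Fisher's exact p = 0.228). Only 4 of the 158 peaks there overlapped a KAP1 peak (2.53%, 0.694 to 6.35%), so peaks with a called KAP1 peak made up little of that excess. A gain of whole chromosome 14 would spread peaks along it, but 83.5% lay beyond 80 Mb, and a gain of that distal part cannot be told apart from other causes because the A3 to E14 ratio of KAP1 peaks there was 0.678 with few E14 peaks (Fisher's exact p = 0.0772). On chromosome 1 the A3 KAP1 share was 1.31 times the E14 share, in the direction that a gain of the chromosome predicts, but across other chromosomes the KAP1 and ZFP57 ratios agreed on chromosome 8 (1.51 each) and went opposite ways on chromosome 11 (2.12 and 0.463), so the KAP1 ratio by itself does not settle a gain, and an altered copy number stays open because the input libraries were not analysed here.

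The A3 KAP1 list was 10295 peaks long and the E14 list 1334. If both were the same ranking stopped at different depths, nearly all wide E14 peaks should recur in A3, but 57.7% of the wider part did (54.3 to 61.0%). By width the share was 24.8% of E14 peaks of 300 bp, 52.7% of those of 450 bp, 68.9% of those of 600 bp and 69.8% of those of 750 bp, but 43.1% (29.3 to 57.8%) of those over 750 bp. Weak calls, background and line differences stay open for the calls in E14 alone.

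Other chromosome shares differed between the lines without further weighing. The A3 over E14 ratio for ZFP57 was 0.385 on chromosome 6 and 0.463 on chromosome 11. For KAP1 it was 1.31 on chromosome 1, 1.51 on chromosome 8, 2.12 on chromosome 11, 0.702 on chromosome 12, 0.678 on chromosome 13, 0.351 on chromosome X and 0.130 on chromosome Y. These are ratios of shares of lists of unlike length, not of peak counts. The A3 and E14 KAP1 lists held 176 and 65 peaks on chromosome X and 9 each on chromosome Y.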

How the results depend on the processing

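Every overlap stayed above chance (one-sided permutation p = 0.001) under each alternative run: reciprocal overlap of 50%, a distance of 1 kb, the wider part of each list, autosomes alone, no peaks over 1500 bp, no chromosomes 1, 2, 8 and 14, and a chance level from moving peaks by 50 to 500 kb. The last 3 were added after seeing the data, as were all alternatives for the sites called in all lists. In the wider part the line-shared ZFP57 peaks rose to 7.91% of A3 and 15.6% of E14, from 3.77% and 9.30%, and the E14 ZFP57 peaks with KAP1 to 39.9% from 26.6%. Without chromosomes 1, 2, 8 and 14 the line-shared share of A3 ZFP57 peaks was 5.91%, with 49 of 829 peaks shared against 56 of 1485 in the whole list. The odds ratio of KAP1 overlap ranged in A3 from 77.2 at 1 kb to 171 on autosomes, and in E14 fell to 12.5 in the wider part. Sites called in all lists numbered 32 in the wider part, 35 without wide peaks, 37 on autosomes, 33 without the 4 chromosomes and 38 at 1 kb, against 38, and a reciprocal overlap was not defined for sites of 4 lists. The E14 ZFP57 and KAP1 chromosome spreads did not differ in the wider part either (permutation p = 0.954). No paired analysis was possible because each group has 1 library and the labels give no replicate numbers, and for the same reason no replicate could be left out. Alternatives for peak scores, gene context, gene lists, motif and base composition were not run. With no read counts or scores, the depth behind a peak is unknown, and an absent peak does not show absent binding.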

Other observations

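The densest 1 Mb windows of KAP1 peaks in A3 were on chromosome 7 from 30 to 31 Mb, with 27 peaks, and from 29 to 30 Mb, with 22, on chromosome 6 from 128 to 129 Mb and chromosome 8 from 87 to 88 Mb, with 24 each, on chromosome 16 from 3 to 4 Mb, with 21, and on chromosome 5 from 136 to 137 Mb, with 20. Random placements gave at most 18 in any window. These windows held 0 to 2 peaks each of the shorter E14 KAP1 list. In E14 the densest was chromosome X from 120 to 121 Mb, with 12 KAP1 peaks and 7 ZFP57 peaks, against at most 5 and 4 in any window of that chromosome in random placements. The A3 lists had 5 KAP1 peaks and 9 ZFP57 peaks there, and placements of the A3 ZFP57 list gave at most 4 on that chromosome. Across all chromosomes those placements gave up to 13 in a window, a value that chromosome Y, with a span of 2.87 Mb, reached by itself. That maximum therefore cannot judge the 9 peaks on chromosome X. Chromosome 4 from 145 to 147 Mb held 9 and 8 E14 KAP1 peaks in its 2 windows and 11 and 13 in A3. Random placements gave at most 8 E14 and 18 A3 KAP1 peaks in any window.

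ZFP57 peaks were then set against the density of A3 KAP1 peaks. Of the A3 ZFP57 peaks, 38.2% (35.6 to 40.8%) were in the third of autosomal 5 Mb windows with the fewest A3 KAP1 peaks, against 23.4% (19.9 to 27.1%) of the E14 ZFP57 peaks and, by the choice of windows, 13.2% of the A3 KAP1 peaks themselves. Across the 485 windows, which are not independent replicates, the count of A3 ZFP57 peaks fell as that of A3 KAP1 peaks rose (Pearson r = -0.125, adjusted permutation p = 0.0059; Spearman rho = -0.123, adjusted p = 0.0082). E14 ZFP57 peaks went the other way (r = 0.257, adjusted p = 0.0003; rho = 0.263, adjusted p = 0.0004). The adjustment covers 8 such correlations.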
